A study of Mus musculus with 15 samples.

How the data were processed

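Kidney RNA of male C57BL/6J mice was measured in 15 libraries, 5 each of sham, I/R and I/R plus NAT (called NAT), grouped by the labels alone. Per the labels' protocols, polyadenylated RNA was sequenced on a BGISEQ instrument, each library in a single lane. The authors deposited 1 table of expression values for 18443 genes by NCBI gene ID. The labels state no unit for these values, so the unit of the deposited table, FPKM, was inferred from the values. Column totals differed with a CV of 7.42%, and totals of FPKM multiplied by transcript length less 150 bases with a CV of 1.67%, using lengths for 96.5% of genes. The extraction protocol names GRCm38.p6 and the submitters' processing notes name mm9; the aligner, the counting tool and their versions are not given in the sources used here. Of the gene IDs 18390 (99.7%) matched the RefSeq annotation of GRCm38.p6 and 53 did not; 82 genes were at 0 in every library. All 15 columns were used. Transcripts of the mitochondrial genome were not analysed here.

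FPKM gives no read totals. Relative depth was estimated from the smallest steps between low values, which scale with the value of 1 read, so low values carry a counting error that could not be computed.

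The groups, the comparisons, the gene lists, the thresholds and the first set of other settings were chosen before the data were examined. Genes with at least 1 FPKM in at least 5 libraries (13045) were tested on log2(FPKM + 1) with limma 3.58.1 and statmod 1.5.0 in R 4.3.3, as a model of 3 groups with 12 residual degrees of freedom, an intensity trend and robust variance moderation. P-values were adjusted by the Benjamini-Hochberg method within each comparison, at 0.05. Because values were FPKM, no count model was used. Of 29 gene lists with 627 genes (587 in the table), 23 had at least 5 tested members and were tested with camera at a preset correlation between genes of 0.01, with camera at an estimated correlation and with fry beside it. Counts of changed members are given as adjusted over all tested genes, over the list alone, and after centring. List scores per library, printed as mean log2(FPKM + 1) less the sham mean, were tested as mean z-scores by exact permutation over all 252 assignments and adjusted over 24 lists. These were the 23 and a list of 27 transcripts known for nuclear retention, which was added after the data were seen. Library measures were tested in the same way over 21 tests.

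Genes are named by 3 rules. The first took the 8 largest rises and 8 largest falls among genes with adjusted p under 0.05, a mean of at least 1 FPKM and no overlap of the 5 values of each group, leaving out predicted and clone-named genes, or the 5 smallest p where no gene passed. The second took up to 3 members of smallest p of each list that passed or had at least 3 changed members. The third was a panel of Havcr1, Lcn2, Spp1, Vcam1, Col1a1, Fn1, Acta2, Tgfb1, Slc34a1, Lrp2, Umod, Egf, Ccl2, Il1b, Adgre1, Cd3e, Tacr1, Bax and Cycs. A few genes that these rules name are not reported here.

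The share of changed genes moved back was compared with 1000 simulations without effect (seed 1) and with 20 divisions that used separate I/R libraries on each side. Recovery was tested on simulated data, with changes only in genes whose mean log2(FPKM + 1) was above log2(10). Of genes changed by a factor of 2, 83.6% were recovered for I/R against sham, 82.1% for NAT against I/R and 86.6% for NAT against sham. Of genes changed by a factor of 1.5, these shares were 44.8%, 53.7% and 49.3%. A matrix list moved by 0.5 log2 units was called, with 0 of the other lists. Simulated genes varied independently, while this list had an estimated correlation of 0.823 in the data. False calls by camera at such a correlation were therefore not tested. Group labels were also compared with other splits of the libraries, 100 in all with the real one.

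Other settings chosen beforehand were quantile normalization, no expression filter, a pseudocount of 0.1, models of 2 groups, a block on replicate number, weights per library, a log2 threshold of 1, a threshold of 0.01, genes of mean at least 10 FPKM, separate I/R libraries, and leaving out each library. Median centring, adjustment of each library for GC content and length by splines with 4 degrees of freedom (98.7% of tested genes), and leaving out both libraries numbered 2 were added after the data were seen. Tables were prepared with Python 3.11.15.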

Results

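Polyadenylated RNA was sequenced from kidneys of male C57BL/6J mice aged 6 to 8 weeks, to study how N-acetyl-tryptophan (NAT), an acetylated form of the amino acid tryptophan, acts in kidney protection. In the ischemia-reperfusion (I/R) model, both renal pedicles were clamped for 30 min and blood flow was then restored; the I/R mice belonged to a 28 day model. The 15 libraries were 5 from sham mice, 5 from I/R mice and 5 from I/R mice given NAT at 7.5 mg/kg, called NAT libraries. The labels do not say that each library came from a separate animal, so p-values measure the spread between these libraries, technical spread included. Expression values were FPKM, read fragments scaled by transcript length and library size, and gave no read totals. They summed to between 767332 and 983000 per library. The value of 1 read, estimated from the lowest values, was 1.41 ± 0.295 times the reference step in I/R, 1.05 ± 0.108 in sham and 0.961 ± 0.0772 in NAT libraries (mean ± SD, n = 5), a larger step standing for fewer reads. The exact permutation p was 0.0397 for I/R against sham (adjusted 0.0641) and 0.0159 for NAT against I/R (adjusted 0.0303).

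Most variation between libraries lay along 1 axis: the first principal component carried 78.6% of the variance. Kap, an androgen-regulated transcript of the proximal tubule, held 22.6% ± 1.61 of all FPKM in sham, 10.3% ± 5.38 in I/R and 19.6% ± 2.66 in NAT libraries. The I/R libraries also stood apart in measures that were not built as markers of injury or cell type. All are computed from expression, so they may follow the tissue as well as the handling of RNA or libraries. The GC slope is the slope on GC content of a library's difference from the sham mean, with transcript length and sham level in the model. The sham libraries therefore average 0 by construction. It was 0.253 ± 0.0389 log2 units per 10 points of GC in I/R libraries (0.211 to 0.308) and at most 0.0824 in the other 10. The SD of the 78 ribosomal protein genes around their sham means was 0.348 to 0.486 in I/R libraries and at most 0.215 in the others. The sham libraries form these means, which makes their own SD smaller and tilts the permutation test of I/R against sham toward a difference. The NAT libraries, which did not enter these means, lay at 0.107 to 0.215. A score of 27 transcripts known for nuclear retention, listed after the data were seen, was 1.03 ± 0.236 in I/R and 0.00726 ± 0.267 in NAT libraries, against 0 ± 0.243 in sham. This score was not centred, and the median log2 value of all tested genes was itself 3.73 ± 0.126 in I/R and 3.25 ± 0.0737 in sham libraries. The GC slope, the ribosomal SD and the nuclear retention score each gave exact permutation p = 0.00794 for I/R against sham and for NAT against I/R (adjusted 0.0208), the smallest value that 252 assignments allow. They separated the same libraries as the proximal tubule score did in both comparisons, and as the matrix score did for I/R against sham. NAT library 2 differed from this pattern, with injury and immune genes as high as in I/R libraries and a GC slope, ribosomal SD and nuclear score below all of them.

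**Figure D1:**
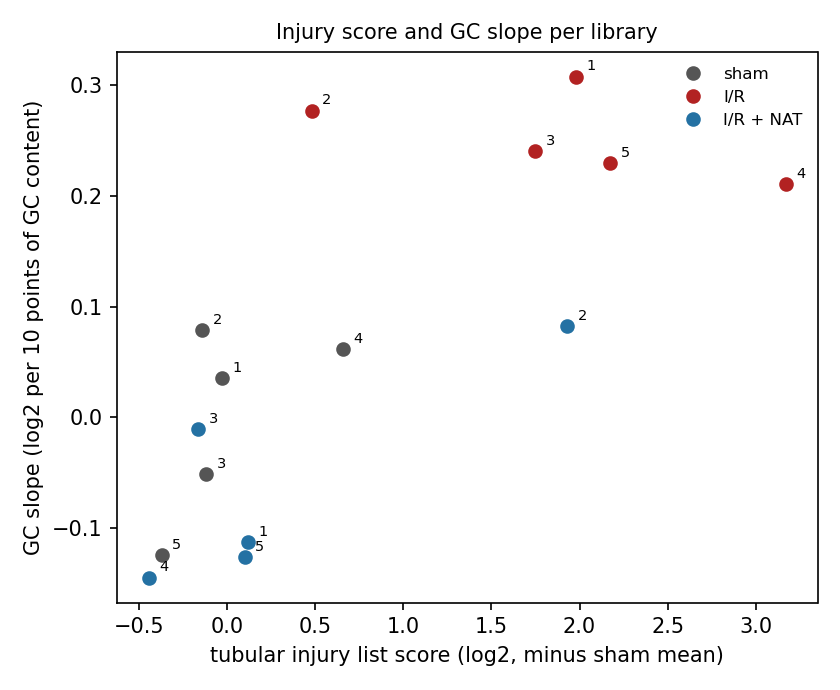
Tubular injury score (x, mean log2 difference from the sham mean) against GC slope (y) for each of the 15 libraries, numbered by replicate. The GC slope is the slope on GC content of a library's difference from the sham mean, in log2 per 10 points of GC. All 5 I/R libraries lie at a slope of 0.211 or more, I/R library 2 has an injury score of 0.479, and NAT library 2 combines an injury score of 1.93 with a slope of 0.0824.

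Collagen genes and genes of injured tubule rose in I/R against sham kidneys. Col3a1 averaged 176 ± 103 FPKM in I/R and 10.5 ± 9.49 in sham libraries, a log2 fold change of 4 (SE 0.80, adjusted p = 0.00052). Col1a1 averaged 125 ± 84.9 against 8.54 ± 8.13 (log2 fold change 3.72, SE 0.85). Enzymes of the proximal tubule fell: Cyp4b1, a fatty acid hydroxylase, averaged 189 ± 85.5 against 1970 ± 392 FPKM (log2 fold change -3.52, SE 0.35) and Fbp1, an enzyme of gluconeogenesis, 77.7 ± 44.2 against 633 ± 135 (log2 fold change -3.17, SE 0.34).

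Of 13045 genes tested with limma, 9609 passed an adjusted p of 0.05, with 7464 higher and 2145 lower in I/R. The median log2 fold change of all tested genes was 0.446. After each library was centred on its own median, 4025 genes were higher and 4658 lower, and quantile normalization gave 4125 and 4375. The share of higher genes was therefore 77.7% before and 46.4% after centring. Where changed list members are counted, centred counts are given beside the counts as deposited. Centred fold changes are given for some genes only, and all other fold changes and FPKM are as deposited. At an absolute log2 fold change of at least 1, 3513 genes passed, 2926 higher and 587 lower. In 53.9% of the tested genes all 5 I/R values lay outside the range of the 5 sham values on the same side, where chance gives 0.794%.

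Among the other largest rises that separated the groups were Krt19 (75.8 ± 53.4 against 4.45 ± 4.32 FPKM), a keratin of injured tubule cells, S100a6 (542 ± 355 against 39.3 ± 31.0), a calcium-binding protein, and Tmsb10 (2480 ± 1710 against 238 ± 167), an actin-binding peptide. Sprr1a, Psca and Spi1, the last a transcription factor of myeloid cells, had log2 fold changes of 3.68, 3.35 and 3.24, and 3.20, 2.87 and 2.76 after centring. The other largest falls were Ces1d, Hsd3b4, Cyp2e1 and Apom, with log2 fold changes of -3.26, -2.99, -2.76 and -2.73, and -3.74, -3.47, -3.24 and -3.21 after centring. Ugt1a7c fell by 4.05 on the log2 scale, but it shares exons with the other Ugt1a genes, so its value is uncertain. Tmem254c, which has near-identical copies, was listed at 0 in 4 I/R libraries and at 3.25 FPKM in I/R library 4, and averaged 19.7 ± 8.97 in sham libraries.

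Tubular injury genes rose: 20 of 24 tested members were higher and 1 was lower, the same counts adjusted over the list alone, and 17 and 2 after centring. Havcr1, the kidney injury molecule, averaged 56.3 ± 83.5 FPKM in I/R and 2.09 ± 2.52 in sham libraries (log2 fold change 3.29, SE 0.88, adjusted p = 0.0039). Lcn2, which encodes the injury marker NGAL, averaged 510 ± 541 against 19.8 ± 30.9 (log2 fold change 4.94, SE 1.14), and Spp1, osteopontin, 4760 ± 4890 against 578 ± 234. Vcam1, an adhesion molecule, Krt18 and Sox4 had log2 fold changes of 2.82, 2.30 and 2.41. The spread between I/R libraries was wide: Havcr1 was 204 in I/R library 4, 1.62 in I/R library 2 and 19.3 to 29.9 in the other 3, and Lcn2 was 61.7 in I/R library 2 and 1446 in I/R library 4, and sham library 4 reached 74.8. Against other genes the list did not pass camera (adjusted p = 0.154, and adjusted p = 0.836 with an estimated correlation). At the preset correlation it passed without I/R library 2 (adjusted p = 0.0373) and after centring (0.00188). Its score per library was 1.91 ± 0.966 in I/R and 0 ± 0.390 in sham (exact permutation p = 0.0159, adjusted 0.0238). The groups overlapped, with I/R library 2 at 0.479 below sham library 4 at 0.660. Spp1 was 474 FPKM in I/R library 2, within the sham range of 420.5 to 989, and 13114 in I/R library 4.

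Extracellular matrix genes rose together, with 32 of 34 members higher and 0 lower (33 adjusted over the list alone, 30 after centring; camera adjusted p = 0.00482, adjusted p = 0.836 with an estimated correlation). Col4a2 averaged 96.9 ± 20.7 against 35.1 ± 6.90 FPKM and Col5a2 15.3 ± 5.99 against 4.11 ± 0.460. Fn1, fibronectin, rose from 5.49 ± 2.25 to 29.5 ± 6.95 FPKM, Acta2, the actin of myofibroblasts and smooth muscle, from 29.9 ± 9.62 to 110 ± 42.9, and Tgfb1, a profibrotic cytokine, from 8.12 ± 1.60 to 36.5 ± 17.8. Fbn1, fibrillin, had a log2 fold change of 1.59 (SE 0.29).

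Immune genes were also higher in I/R. All 25 macrophage and dendritic cell genes rose (25 adjusted over the list alone, 21 after centring), among them Cd14 (28.7 ± 19.9 against 3.55 ± 2.15 FPKM), Cx3cr1 and Aif1. All 15 T and NK cell genes rose (15 over the list alone, 9 after centring), with Cd2 at 16.3 ± 12.3 against 1.32 ± 1.30. So did 5 of 6 B and plasma cell genes (5 and 5), with Cd79a at 11.2 ± 8.53 against 1.87 ± 0.287. I/R library 2 did not share the T and NK cell rise, with a score of 0.0424 within the sham range of -0.340 to 0.586. Its macrophage score of 0.457 was below that of sham library 4 (0.906). Adgre1, the macrophage antigen F4/80, and Cd3e, a chain of the T cell receptor complex, had log2 fold changes of 1.44 and 1.5 (adjusted p = 0.019 and 0.018). After centring these were 0.95 and 1.02, with adjusted p = 0.065 and 0.062. The Adgre1 call was also lost without I/R library 4 (adjusted p = 0.0532). Against other genes these lists had camera adjusted p of 0.0852, 0.154 and 0.246, and each had adjusted p = 0.836 with an estimated correlation. At the preset correlation the macrophage list passed without I/R library 2 (0.0232), without NAT library 2 (0.00926) and after centring (8.09e-05), and the T and NK cell list without I/R library 2 (0.0289) and after centring (0.00318).

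Cytokine, chemokine and NF-kB genes rose in 24 of 25 cases (24 over the list alone, 22 after centring; camera adjusted p = 0.0477, adjusted p = 0.836 with an estimated correlation). Nfkb2 averaged 46.2 ± 26.0 against 8.56 ± 3.61 FPKM, Icam1 66.0 ± 35.6 against 12.7 ± 4.67 and Ccl2, a monocyte chemoattractant, 31.1 ± 35.4 against 2.12 ± 3.33, with Il1b at a log2 fold change of 1.57 (SE 0.46). Ccl2 was 92.7 in I/R library 4 and 2.25 to 23.0 in the other I/R libraries, and I/R library 2 lay within the sham range of 0.16 to 8.02. The camera call was lost without any of I/R library 1, 3, 4 or 5, sham library 1, 3 or 5, or NAT library 3 or 4 (adjusted p 0.0501 to 0.109). Interferon response genes rose in 22 of 24 cases (24 over the list alone, 20 after centring; camera adjusted p = 0.00597, adjusted p = 0.836 with an estimated correlation). Stat2, a transcription factor of interferon signalling, averaged 28.9 ± 5.39 against 6.98 ± 1.65 and Ifit1 9.01 ± 1.82 against 1.95 ± 0.738. Of 14 complement genes 10 rose and 2 fell (11 and 2 over the list alone, 9 and 2 after centring; camera adjusted p = 0.542), with C1ra higher at a log2 fold change of 1.97 and Cfb lower at -0.66.

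Every one of the 32 proximal tubule genes fell (32 over the list alone, 32 after centring; camera adjusted p = 7.68e-20, adjusted p = 0.37 with an estimated correlation). Slc34a1, the sodium-phosphate cotransporter of the proximal tubule, averaged 1730 ± 629 against 3510 ± 543 FPKM (log2 fold change -1.10, SE 0.26), and Lrp2, the endocytic receptor megalin, 34.8 ± 8.56 against 72.7 ± 12.7. Cyp2e1, a cytochrome P450, averaged 197 ± 70.8 against 1300 ± 239. The score was -1.60 ± 0.592 in I/R and 0 ± 0.0940 in sham libraries (exact permutation p = 0.00794, adjusted 0.0173). The nuclear retention score moved with this group, at 0.634 or more in every I/R library.

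Mitochondrial and lipid oxidation genes fell as well. Of 30 nuclear-encoded oxidative phosphorylation genes 27 fell and 1 rose (27 and 1 over the list alone, 28 and 0 after centring; camera adjusted p = 1.67e-15, adjusted p = 0.37 with an estimated correlation). Sdha, a subunit of succinate dehydrogenase, averaged 40.0 ± 11.1 against 152 ± 23.3 FPKM, Cox5a 136 ± 69.8 against 562 ± 44.0, and Cycs, cytochrome c, 134 ± 23.0 against 233 ± 34.0. Of 28 fatty acid oxidation and peroxisome genes 23 fell and 0 rose (24 over the list alone, 25 after centring; camera adjusted p = 1.19e-14, adjusted p = 0.37 with an estimated correlation). Echs1 averaged 27.9 ± 8.88 against 99.7 ± 15.1 and Acads 28.2 ± 12 against 102 ± 14. Of 30 oxidative stress and ferroptosis genes 17 fell and 4 rose (17 and 4 over the list alone, 22 and 1 after centring; camera adjusted p = 2.83e-07, adjusted p = 0.311 with an estimated correlation). The falls named were in protective genes: Fth1, the ferritin heavy chain, averaged 2000 ± 630 against 5960 ± 485, Gpx1, a glutathione peroxidase, 643 ± 219 against 2530 ± 258, and Prdx1, a peroxiredoxin, 278 ± 46.9 against 738 ± 94.0.

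In tryptophan, kynurenine and NAD metabolism, 13 of 27 genes fell and 6 rose (13 and 6 over the list alone, 16 and 5 after centring; camera adjusted p = 0.00181, adjusted p = 0.37 with an estimated correlation). Qprt, which makes the NAD precursor nicotinate mononucleotide from quinolinate, averaged 8.86 ± 2.89 against 38.8 ± 7.29 FPKM, and Ddc, aromatic amino acid decarboxylase, 8.47 ± 4.02 against 36.1 ± 6.52. The score of this list was -0.353 ± 0.290 in I/R and 0 ± 0.0535 in sham libraries, and the exact permutation test on z-scores did not pass (p = 0.421, adjusted 0.505).

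The remaining lists did not pass camera (adjusted p 0.0852 to 0.693). Fry tests against no change and was run on values that were not centred. It called immediate early (adjusted p = 0.00178), apoptosis and p53 (0.00259), endothelium (0.0102), circadian (0.0102) and cell cycle (0.0231) genes up, but not the other remaining lists (0.0952 to 0.989). It also called up the tubular injury, macrophage, T and NK cell, B and plasma cell and complement lists above (0.00259 to 0.0112). Endothelial genes rose in 14 of 17 cases (15 over the list alone), but only 5 rose and 1 fell after centring; Eng averaged 106 ± 12.8 against 47.2 ± 11.4 FPKM and Nos3 6.42 ± 0.985 against 2.5 ± 0.503. Immediate early genes rose in 16 of 17 cases (16 over the list alone, 11 after centring), with Ier2 at 26.4 ± 11.2 against 7.79 ± 1.75. At the preset correlation this list passed without I/R library 2 (adjusted p = 0.0272) and after centring (0.00318), and it had adjusted p = 0.836 with an estimated correlation. Of 18 cell cycle genes 13 rose (11 over the list alone, 7 with 3 lower after centring), with Plk1 at 3.96 ± 1.05 against 1.15 ± 0.594. Of 34 apoptosis and p53 genes 21 rose and 5 fell (22 and 5 over the list alone, 14 and 11 after centring). Casp8, an initiator caspase, had a log2 fold change of 1.27, Bid -1.26, and Bax 0.78, or 0.79, -1.75 and 0.30 after centring. Mdm2 had a log2 fold change of 0.62, which after centring was 0.14 (adjusted p = 0.11).

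Lists of the distal nephron, podocytes and stress responses went both ways. Of 26 loop, distal tubule and collecting duct genes 6 rose and 4 fell (4 and 2 over the list alone, 2 and 8 after centring). Umod, uromodulin of the thick ascending limb, averaged 461 ± 150 against 782 ± 199 FPKM (log2 fold change -0.79, SE 0.32, adjusted p = 0.036). This call was lost without any of sham library 1, 2, 3 or 5 or I/R library 1 or 4 (adjusted p 0.061 to 0.1), after quantile normalization (0.0985) and after GC and length adjustment (0.0577). Egf, made in the distal tubule, had a log2 fold change of -1.66 (SE 0.63, adjusted p = 0.026, or 0.0518 without sham library 3), with 4.21 FPKM in I/R library 4 and 55.2 to 125 in the other I/R libraries. Podocyte genes rose in 7 of 13 cases and fell in 3 (9 and 3 over the list alone, 2 and 3 after centring), with Podxl at -0.63 and Cdkn1c at 1.32. Unfolded protein response genes rose in 8 of 19 cases and fell in 5 (8 and 5 over the list alone, 3 and 9 after centring), Herpud1 falling from 135 ± 15.9 to 42.8 ± 6.14. Circadian genes rose in 6 of 18 cases and fell in 1 (6 and 1 over the list alone, 2 and 4 after centring), with Hlf at a log2 fold change of -1.58. Cholesterol synthesis genes rose in 5 of 18 cases and fell in 4 (5 and 4 over the list alone, 1 and 8 after centring), with Fdft1 at a log2 fold change of 0.98, or 0.50 after centring. None of the 6 red blood cell genes passed. For the podocyte, unfolded protein, circadian and red blood cell lists the median and mean were positive and camera's direction, relative to other genes, was down, and for the loop and cholesterol lists the median alone was positive. At the preset correlation the loop list passed camera without I/R library 2 (adjusted p = 0.0272), the cholesterol list without I/R library 2 (0.0338) or sham library 2 (0.038), and the unfolded protein list without I/R library 4 (0.0271). Each of the 3 had adjusted p = 0.836 with an estimated correlation.

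**Figure D2:**
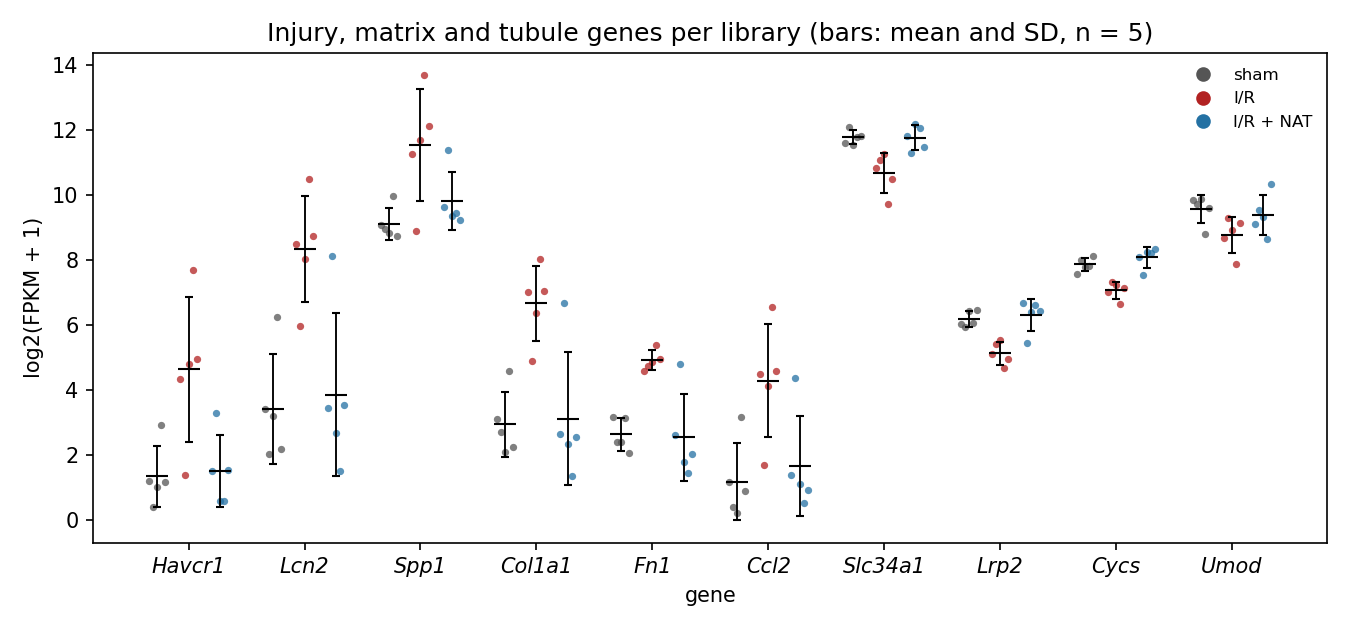
log2(FPKM + 1) of injury genes, matrix genes, a chemokine and tubule genes in each library of the 3 groups, with bars at the mean and SD of 5 libraries. Lcn2 averaged 19.8 FPKM in sham, 510 in I/R and 60.3 in NAT libraries, and the NAT library far above the others for the injury and matrix genes is NAT library 2.

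Proximal tubule enzymes were higher in NAT than in I/R libraries: Cyp4b1 averaged 2100 ± 620 against 189 ± 85.5 FPKM (log2 fold change 3.57, SE 0.35, adjusted p = 5.8e-06). Cyp2e1 averaged 1750 ± 532 against 197 ± 70.8 (log2 fold change 3.14, SE 0.27) and Fbp1 744 ± 244 against 77.7 ± 44.2. Matrix and injury genes were lower: Col1a1 averaged 23.3 ± 43.2 against 125 ± 84.9 FPKM (log2 fold change -3.54, SE 0.85). Lcn2 averaged 60.3 ± 119 against 510 ± 541 (log2 fold change -4.49, SE 1.14) and Havcr1 2.69 ± 3.47 against 56.3 ± 83.5 (log2 fold change -3.13, SE 0.88). For these 3 genes the SD in NAT libraries exceeded the mean because of NAT library 2, which held 101 FPKM of Col1a1, 274 of Lcn2 and 8.77 of Havcr1.

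Of the 13045 tested genes 9347 passed, with 2514 higher and 6833 lower in NAT libraries by limma. The median log2 fold change was -0.382, and after centring 4650 genes were higher and 4096 lower (53.2% higher, against 26.9% before), with 4459 and 4110 after quantile normalization. At an absolute log2 fold change of at least 1, 659 genes were higher and 2708 lower. All 5 NAT values lay on 1 side of the 5 I/R values in 36.7% of the genes, where chance gives 0.794%.

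The largest rises that separated the groups included Ces1d, Apom and Slco1a1, an organic anion transporter of the proximal tubule, with log2 fold changes of 3.39, 3.23 and 3, and 3.80, 3.64 and 3.41 after centring. Ugt1a7c and Tmem254c also rose, with the same uncertainty over shared reads. The largest falls included Sprr1a (10.8 ± 11.8 against 92.5 ± 53.4 FPKM), Spon1 (4.86 ± 5.62 against 34.4 ± 9.91) and Coch. They also included Nupr1, a stress-induced transcription regulator (70.6 ± 79.2 against 369 ± 105), Scarf2 (11.9 ± 11.8 against 74.6 ± 24.8) and Adgrg3 (4.09 ± 1.96 against 35.3 ± 10.3). Ccdc152 and Cnbd2 had log2 fold changes of -3.15 and -2.97, but they overlap Selenop and Scand1, whose reads may be counted with them.

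Proximal tubule genes rose in 31 of 32 cases (32 adjusted over the list alone, 32 after centring; camera adjusted p = 6.48e-16, adjusted p = 0.69 with an estimated correlation). Slc34a1 averaged 3560 ± 903 against 1730 ± 629 FPKM and Lrp2 81.5 ± 23.3 against 34.8 ± 8.56. The GC slope, the ribosomal SD and the nuclear retention score separated NAT from I/R libraries in the same way as these genes' score did. Fatty acid oxidation genes rose in 22 of 28 cases (22 over the list alone, 25 after centring; camera adjusted p = 1.79e-12, adjusted p = 0.722 with an estimated correlation), with Echs1 at 111 ± 24.2 against 27.9 ± 8.88. Of 30 oxidative phosphorylation genes 25 rose and 1 fell (25 and 1 over the list alone, 27 and 0 after centring; camera adjusted p = 8.69e-12, adjusted p = 0.726 with an estimated correlation). Sdha averaged 176 ± 39.0 against 40.0 ± 11.1 and Cycs 274 ± 54.7 against 134 ± 23.0. NAT library 2 lay within the I/R range of both scores, at -0.476 for fatty acid oxidation and -0.330 for oxidative phosphorylation. Of 30 oxidative stress and ferroptosis genes 18 rose and 2 fell (18 and 2 over the list alone, 25 and 0 after centring; camera adjusted p = 5.9e-07, adjusted p = 0.355 with an estimated correlation). Fth1 averaged 5380 ± 355 against 2000 ± 630 and Gsr, glutathione reductase, 42.7 ± 10.9 against 12.7 ± 1.61.

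Matrix genes fell in 31 of 34 cases and 0 rose (32 over the list alone, 30 after centring; camera adjusted p = 0.00186, adjusted p = 0.944 with an estimated correlation). Col4a2 averaged 32.9 ± 14.5 against 96.9 ± 20.7 FPKM and Col6a3 2.75 ± 3.05 against 11.7 ± 2.18. Fn1, Acta2 and Tgfb1 fell by 2.37, 1.93 and 1.83 on the log2 scale. Interferon response genes fell in 21 of 24 cases (21 over the list alone, 20 after centring; camera adjusted p = 0.00374, adjusted p = 0.944 with an estimated correlation), with Stat2 at 7.93 ± 4.21 against 28.9 ± 5.39. Cytokine, chemokine and NF-kB genes fell in 24 of 25 cases (25 over the list alone, 17 after centring; camera adjusted p = 0.0384, adjusted p = 0.944 with an estimated correlation). Icam1 averaged 15 ± 12.7 against 66.0 ± 35.6 and Ccl2 4.70 ± 8.24 against 31.1 ± 35.4, with Il1b at a log2 fold change of -1.40 (adjusted p = 0.013, or 0.0733 after quantile normalization). That camera call was lost without I/R library 4 (adjusted p = 0.101) or without NAT library 1, 3, 4 or 5 (0.0548 to 0.0592). NAT library 2 stood with the I/R libraries in these groups, with a matrix score of 2.14 against -0.954 to -0.0574 in the other 4 NAT libraries.

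Tubular injury genes fell in 18 of 24 cases and 1 rose (18 and 1 over the list alone, 14 and 3 after centring). S100a6 averaged 63.0 ± 91.6 against 542 ± 355 FPKM, Vim 52.3 ± 61.4 against 197 ± 91.6 and Igfbp7 1730 ± 383 against 3220 ± 777. NAT library 2 raised these means, with S100a6 at 226 and Vim at 162 FPKM, and stood with the I/R libraries for injury and immune genes. Vcam1 fell by 2.35 on the log2 scale. Spp1 had a log2 fold change of -1.72 (SE 0.67, adjusted p = 0.031), which did not pass after centring (0.068) or without any of I/R library 3, 4 or 5 or NAT library 1, 3, 4 or 5 (0.0551 to 0.0859). Macrophage genes fell in 23 of 25 cases (23 over the list alone, 18 after centring), T and NK cell genes in 12 of 15 (13 and 10) and B and plasma cell genes in 5 of 6 (5 and 4). Examples were Csf1r, the receptor of a macrophage growth factor, at 21.1 ± 17.5 against 57.7 ± 12.3, Cd2 at 2.22 ± 3.11 against 16.3 ± 12.3 and Cd79a at 2.84 ± 1.5 against 11.2 ± 8.53. Cd3e had a log2 fold change of -1.39 (adjusted p = 0.028, or 0.071 after centring and 0.0546 to 0.0625 without NAT library 1, 3, 4 or 5), and Adgre1 -0.91 (adjusted p = 0.12, or 0.000651 without NAT library 2). These 4 lists did not pass camera, with adjusted p of 0.299, 0.0804, 0.163 and 0.299, and each had adjusted p = 0.944 with an estimated correlation. At the preset correlation the macrophage list passed without I/R library 2 (0.0181) or NAT library 2 (0.0026), and the T and NK cell list without I/R library 2 (0.0257). After centring the tubular injury, macrophage and T and NK cell lists passed, with 0.0202, 0.000665 and 0.012.

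Of 27 tryptophan, kynurenine and NAD genes 9 rose and 10 fell (9 and 10 over the list alone, 14 and 5 after centring; camera up with adjusted p = 0.0246, adjusted p = 0.791 with an estimated correlation). Qprt averaged 38.3 ± 9.15 against 8.86 ± 2.89 FPKM, Ddc 39.9 ± 13.0 against 8.47 ± 4.02 and Acmsd, which diverts the kynurenine pathway from NAD synthesis, 47.0 ± 17.1 against 6.97 ± 2.13. The camera call was lost without I/R library 4 (adjusted p = 0.101) and after centring (0.0939). Loop, distal tubule and collecting duct genes rose in 7 of 26 cases and fell in 4 (4 and 2 over the list alone, 10 and 2 after centring; camera up with adjusted p = 0.0306, adjusted p = 0.944 with an estimated correlation). Calb1 averaged 119 ± 53.7 against 25.5 ± 15.2. That call was lost without I/R library 4 (0.527), without NAT library 3 (0.055) and after centring (0.0939). Cholesterol synthesis genes rose in 5 of 18 cases and fell in 1 (5 and 1 over the list alone, 11 and 1 after centring; camera adjusted p = 0.0227, or 0.0548 without NAT library 4, adjusted p = 0.919 with an estimated correlation). Sc5d had a log2 fold change of 0.99. Umod had a log2 fold change of 0.61 (adjusted p = 0.094, or 0.015 after centring and 0.0389 without NAT library 4) and Egf of 1.67 (adjusted p = 0.027, or 0.0683 without NAT library 5). I/R library 4 enlarged the Egf fold change, at 4.21 FPKM against 55.2 to 125 in the other I/R libraries.

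The other lists did not pass camera (adjusted p 0.0804 to 0.952). They included endothelium, where 15 of 17 genes fell (15 over the list alone, 9 with 1 higher after centring; adjusted p = 0.0804, or 0.0402 without NAT library 1, 0.0442 without NAT library 2 and 0.0211 after centring). The endothelial list had adjusted p = 0.944 with an estimated correlation. Eng averaged 40.1 ± 15.5 against 106 ± 12.8 FPKM. Immediate early genes fell in 13 of 17 cases (13 over the list alone, 11 after centring; adjusted p = 0.0997, or 0.0257 without I/R library 2 and 0.0138 after centring). The immediate early list also had adjusted p = 0.944 with an estimated correlation. Complement genes fell in 9 of 14 cases and rose in 2 (9 and 2 over the list alone, 7 and 2 after centring), with C1ra at a log2 fold change of -1.88. Apoptosis and p53 genes fell in 21 of 34 cases and rose in 5 (21 and 5 over the list alone, 12 and 10 after centring), with Bax at 89.8 ± 20 against 172 ± 23.4 and Bid at 37.9 ± 11 against 12.8 ± 2.74. Unfolded protein response genes rose in 5 of 19 cases and fell in 8 (5 and 8 over the list alone, 7 and 6 after centring), with Herpud1 at 106 ± 12.2 against 42.8 ± 6.14 and Ddit3 at 21.4 ± 7.94 against 48.9 ± 5.02. Cell cycle genes fell in 8 of 18 cases and rose in 1 (7 and 1 over the list alone, 6 and 4 after centring), and circadian genes fell in 8 of 18 and rose in 1 (7 and 1, 4 and 2 after centring). Podocyte genes fell in 5 of 13 and rose in 3 (5 and 3, 2 and 4 after centring), and red blood cell genes fell in 2 of 6 (0 over the list alone, 0 after centring). For the podocyte, unfolded protein and red blood cell lists the median and mean were negative and camera's direction was up. On values not centred, fry called immediate early (adjusted p = 0.00445), circadian (0.00534), endothelium (0.00563), complement (0.0156) and apoptosis (0.0215) genes down, but not the other lists here (0.114 to 0.521). It also called down the tubular injury, macrophage, T and NK cell and B and plasma cell lists above (0.007 to 0.028).

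Scores per library were tested over 24 lists with exact permutation tests on mean z-scores. For I/R against sham 18 lists passed, 14 after centring. For NAT against I/R 12 lists passed, each with adjusted p = 0.0476. The nuclear retention list, added after the data were seen, was among the 18 and among the 12. The proximal tubule score was -0.0332 ± 0.368 in NAT and -1.60 ± 0.592 in I/R (exact p = 0.00794, adjusted 0.0476), and the matrix score 0.0666 ± 1.21 and 2.09 ± 0.571 (exact p = 0.0238, adjusted 0.0476). After centring, and after quantile normalization, 0 of the 24 passed for NAT against I/R. The 12 calls had stood just under the threshold at the same adjusted p, so they could be lost together. The tubular injury score, 0.308 ± 0.936 in NAT and 1.91 ± 0.966 in I/R, did not pass (exact p = 0.0873, adjusted 0.131).

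**Figure D3:**
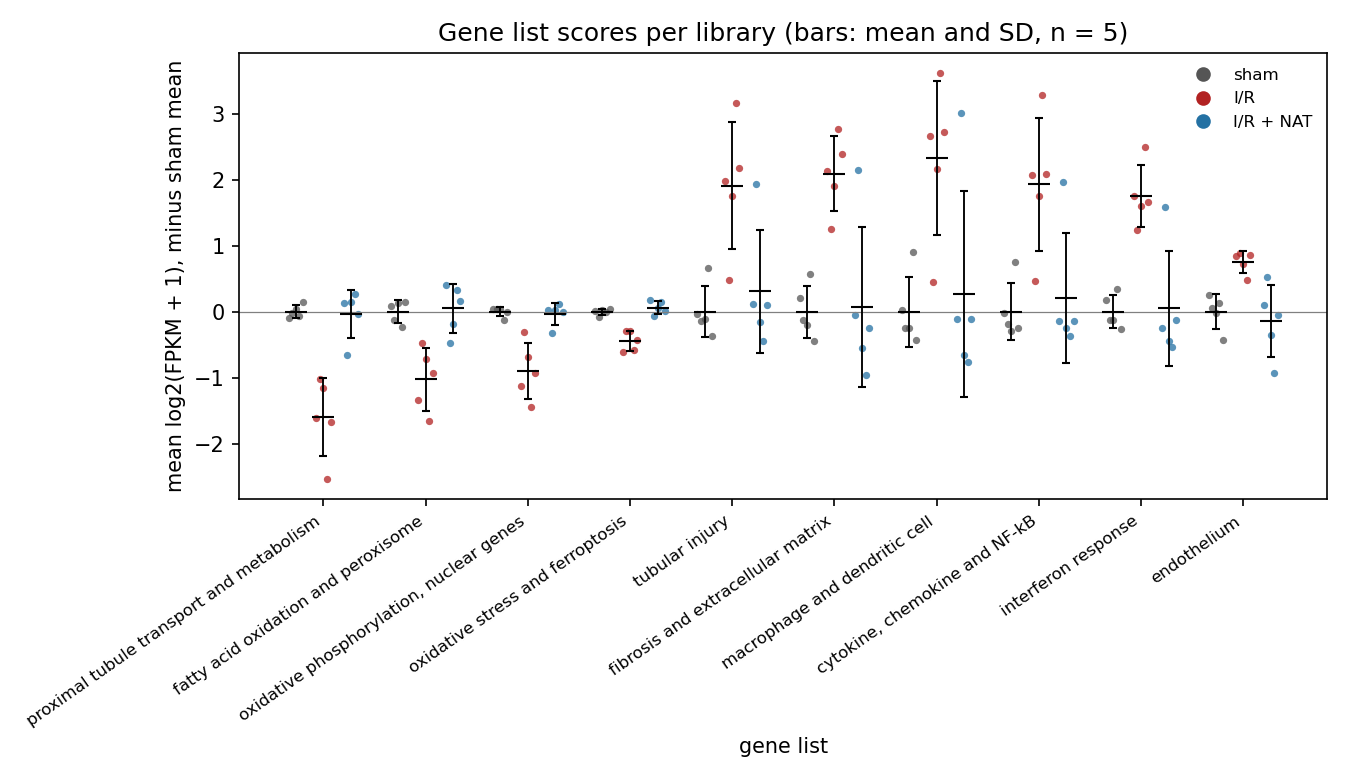
Mean log2(FPKM + 1) of 10 gene lists per library, as the difference from the sham mean, with bars at the mean and SD of 5 libraries. The proximal tubule score averaged -1.60 in I/R and -0.0332 in NAT libraries, and NAT library 2 lies at 1.93 for tubular injury and 3.01 for macrophage and dendritic cell genes.

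The effects of I/R and of NAT were opposite across most genes, in a comparison that uses the same I/R libraries on both sides. Of the 9609 genes changed in I/R, 99.7% had the opposite sign in NAT against I/R (99.85% after centring). Groups simulated with no effect gave a median of 77.2% (95% of simulations between 34.0% and 97.4%), and with separate I/R libraries on each side the share was 99.0% (median of 20 divisions, 90.9% to 99.7%). Across genes, which are not independent replicates, the log2 fold changes had r = -0.973, against a simulated -0.632 (-0.950 to 0.255) and -0.934 with separate I/R libraries (-0.956 to -0.784). The covariance was -0.683, the simulated one -0.0317 and their difference -0.652. Genes higher in I/R and lower under NAT numbered 6591, and genes lower in I/R and higher under NAT 2008. Cyp4b1, Fbp1 and Stat2 were among the genes that passed in both directions.

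The comparison of NAT with sham asked how far NAT kidneys differed from unclamped ones. The proximal tubule genes of the panel had similar means: Slc34a1 averaged 3560 ± 903 in NAT and 3510 ± 543 FPKM in sham libraries (log2 fold change -0.01, SE 0.26) and Lrp2 81.5 ± 23.3 and 72.7 ± 12.7 (log2 fold change 0.12, SE 0.22). Kap, a list member, averaged 177200 ± 27350 in NAT and 215500 ± 17200 in sham libraries (exact permutation p = 0.0476, adjusted 0.0714). Over the whole list 0 of 32 members were called, with a median log2 fold change of -0.0680. Injury genes had wide errors: the log2 fold change was 0.15 for Havcr1 (SE 0.88), 0.44 for Lcn2 (SE 1.14), 0.71 for Spp1 (SE 0.67), 0.47 for Vcam1 (SE 0.79) and 0.18 for Col1a1 (SE 0.85). Without NAT library 2 these were -0.30 for Havcr1, -0.62 for Lcn2, 0.32 for Spp1, -0.30 for Vcam1 and -0.71 for Col1a1, so the direction turned for 4 of the 5 genes. By limma 0 of 13045 genes passed (lowest adjusted p = 0.815), and 782 genes, 5.99%, had an unadjusted p under 0.05; limma with weights per library called 19, with 14 higher and 5 lower. The genes of smallest p were Arl2bp, Avpr1a, a vasopressin receptor, Tubb2a, Elovl6, a fatty acid elongase, and Actg1, with log2 fold changes of 0.41, 0.56, 0.62, 0.54 and 0.65 and adjusted p = 0.82 each, or 0.0438 with weights per library. In the test on simulated changes for this comparison, made in the more highly expressed genes, 86.6% of genes changed by a factor of 2 were recovered. For a factor of 1.5 it was 49.3%, so an absence of smaller changes was not shown. Nor was an absence of changes by a factor of 2 or more shown for genes with wide errors, such as Lcn2 (SE 1.14) and Havcr1 (SE 0.88).

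Other panel genes in NAT against sham were Fn1, Acta2 and Tgfb1 with log2 fold changes of -0.09, -0.10 and 0.11 (SE 0.48, 0.37 and 0.38). Ccl2, Il1b, Adgre1 and Cd3e had 0.49, 0.17, 0.53 and 0.12 (SE 0.86, 0.46, 0.51 and 0.52). NAT library 2 held 19.4, 3.20, 10.15 and 3.77 FPKM of these 4 genes, while every other NAT library lay within the sham range for each. Among NAT libraries, Fn1, Acta2 and Tgfb1 were also highest in NAT library 2. Umod had -0.17 and Egf 0.00 (SE 0.32 and 0.63), and Bax and Cycs had -0.16 and 0.22 (SE 0.15 and 0.16). Camera called 7 lists against other genes with the preset correlation, and each of the 7 had adjusted p = 0.992 with an estimated correlation. These were the unfolded protein (adjusted p = 0.00651, median log2 fold change -0.0468), endothelium (0.00692, -0.0993), oxidative phosphorylation (0.0109, -0.0662), tryptophan and NAD (0.0175, -0.0620), circadian (0.0261, median 0.00484 with a mean of -0.0942) and proximal tubule (0.0475, -0.0680) lists, all down, and cholesterol synthesis (0.0175, 0.282), up. None had a called member over all genes; adjusted over the list alone, 1 cholesterol gene and 1 loop or distal tubule gene passed, both higher. Fry called 0 lists and the exact tests of the 24 scores 0. For the matrix, macrophage, T and NK cell, cytokine, complement, interferon and fatty acid oxidation lists the median and mean were positive and camera's direction was down (adjusted p 0.169 to 0.967). Lost calls by library were endothelium without NAT library 4 (0.616), oxidative phosphorylation without sham library 5 (0.0837) or NAT library 2 (0.741, direction up), and tryptophan without sham library 5 (0.0837) or NAT library 2 (0.533). Further losses were circadian without sham library 5 (0.0837) or NAT library 2 (0.131) or 5 (0.0548), and cholesterol without sham library 2 (0.223) or NAT library 3 (0.0677) or 4 (0.397). The proximal tubule call was lost without sham library 2, 3 or 5, I/R library 1, 3 or 5, or NAT library 2 or 5 (0.0511 to 0.437), and its direction was up without NAT library 2 (0.0695). Without NAT library 2, 11 lists passed, only 3 of them among the 7, and matrix genes were then lower than in sham libraries relative to other genes at the preset correlation (adjusted p = 9.72e-09), with 0 genes called. With all libraries the matrix list had adjusted p = 0.992 with an estimated correlation.

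Tacr1, the receptor of substance P, was listed at 0 in 13 libraries and at 0.03 and 0.02 FPKM in I/R libraries 2 and 4. In the GRCm38.p6 annotation, Havcr1 (NCBI gene 171283) lies on chromosome 11 at 46739822 to 46779578, Lcn2 (16819) on chromosome 2 at 32384637 to 32387739. Col1a1 (12842) lies on chromosome 11 at 94936224 to 94953042, Slc34a1 (20505) on chromosome 13 at 55399622 to 55414695 and Fth1 (14319) on chromosome 19 at 9980600 to 9985111, all as whole genes with exons and introns. The labels name this build in one place and mm9 in another, so the positions hold for GRCm38.p6 only.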

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

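Apart from the test with separate I/R libraries and the splits of group labels, the tests in this part were chosen only after the result was seen. Within groups of 5, the highest or lowest library was marked where its gap to the nearest other exceeded 0.71 of the range, the Dixon limit. This happened in 29 of 147 groups, where chance marks about 1 in 20 (7.35), and 18 of the 29 were NAT library 2.

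NAT library 2 was far from the other 4 NAT libraries in genes of injury, matrix and immune cells. The ratio of gap to range was 0.763 for its tubular injury score, 0.71 for matrix, 0.827 for macrophages, 0.905 for T and NK cells, 0.899 for cytokines, 0.783 for complement and 0.804 for interferon response. It was 0.733 for oxidative phosphorylation, where the library was low, 0.76 for apoptosis, 0.781 for cell cycle and 0.864 for immediate early genes. Among panel genes it was 0.809 for Spp1, 0.79 for Vcam1, 0.757 for Col1a1, 0.767 for Lrp2 (low), 0.777 for Ccl2, 0.863 for Adgre1 and 0.87 for Cd3e.

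Sham library 4 was high for cytokine genes (0.75), unfolded protein genes (0.767), Spp1 (0.725) and Vcam1 (0.744), and low for Umod (0.765) and for the percent of genes at 0 (0.759). I/R library 4 was low for loop and distal tubule genes (0.831; score -1.40 against 0.126 to 0.436) and for Egf (0.747). I/R library 2 was low for podocyte genes (0.782). NAT library 3 was high in total FPKM (0.718), and low in the SD of ribosomal genes (0.807).

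The first pattern weighed was the distance of all 5 I/R libraries from the other 10: 3031 genes were higher and 1214 lower in every I/R library than in any other, 32.5% of genes where chance gives 0.0666%. Handling of RNA or libraries that differed for the I/R group could also set them apart, since the lowest I/R score of nuclear-retained transcripts exceeded the highest other by 0.17, and this was left open. Bias by GC content and length was argued against as the source of most calls. Of calls among genes with known GC content and length, 91.4% were kept after adjustment. The adjustment kept each library's mean level, so a shift of all genes together was not removed and is not covered by this test. Lower depth predicted more genes at 0, and I/R libraries had 2.84 points fewer than sham libraries (difference -2.84). This cannot decide on depth, as genes at 0 also depend on which genes the tissue expresses. The estimated relative depth was 0.737 ± 0.171 in I/R, 0.963 ± 0.102 in sham and 1.05 ± 0.0786 in NAT libraries. Handling was not recorded in the labels, so it may coincide with the I/R group and would then enter both comparisons that use it, with a gap of 0.17 that cannot tell it from injury.

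The second pattern was the position of NAT library 2 near the I/R libraries. An exchange of its label with an I/R library after preparation was argued against with a small margin: every I/R library was closer to its own group than to the NAT group, by at least 0.018 in r. For a single wrong label, the GC slope of NAT library 2 lay 3.3 SDs below the lowest I/R library. This slope had been seen when the test was chosen, so the test alone cannot decide. If the slope follows the tissue, it would go against an animal placed in the wrong group as well. Placement of an animal in the wrong group before preparation might give this library, as might a weak response to NAT, and the data cannot tell these apart. Its injury score of 1.93 exceeded that of the lowest I/R library, I/R library 2 at 0.479, by 1.45. Sham library 4, at 0.660, also exceeded I/R library 2, so passing it does not by itself mark an I/R animal. NAT library 2 was kept in all comparisons.

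The third pattern was the opposite sign of the NAT and I/R effects. The shared I/R libraries alone were argued against, as r was at most -0.784 over 20 divisions with separate libraries. Handling of the I/R group could still give opposite effects, since the product of the 2 effects on nuclear-retained transcripts was -1.05, and this was left open.

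Splits of the libraries showed what other groupings give. For I/R against sham, the real split gave the most changed genes of 100 (9609, highest other 7665), and 1 of 100 splits reached it. For NAT against I/R that was also 1 of 100 (9347, highest other 8860). Chance alone was thus argued against at 1 in 100 for these 2 counts, and not excluded. Splits that mixed the groups still gave up to 7665 and 8860 genes, so a large count did not by itself mark the real groups. For the numbers of lists, 81 of 100 splits reached the 8 of I/R against sham (highest other 18), 68 the 10 of NAT against I/R (highest other 20) and 76 the 7 of NAT against sham (highest other 17), so chance was not excluded. For changed genes in NAT against sham all 100 splits reached the real 0 (highest other 185). Any split reaches 0, so this test could not decide anything for that comparison.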

How the results depend on the processing

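The tests after median centring, after GC and length adjustment and without both libraries numbered 2 were chosen only after the result was seen. The numbers of changed genes kept their size for I/R against sham, NAT against I/R and NAT against sham under quantile normalization (8500, 8569, 0), no filter (11269, 10728, 0), a pseudocount of 0.1 (9595, 9316, 0), 2 groups (9212, 8508, 0), centring (8683, 8746, 0) and GC and length adjustment (9487, 9151, 0). The genes themselves changed more: of the 9609 calls in I/R against sham, 6130 were kept in the same direction under quantile normalization and 6170 after centring, and of the 9347 in NAT against I/R, 6511 and 6610. A log2 threshold of 1 left 3513 and 3367, by its construction. Weights per library gave 19 genes in NAT against sham and 13 lists in I/R against sham; the cause was not tested. An estimated correlation left 0, 0 and 0 lists and fry 18, 16 and 0. Without both libraries numbered 2, 14 lists changed in I/R against sham and 11 in NAT against sham. List scores past the exact test in NAT against I/R fell from 12 to 0 after quantile normalization and to 0 after centring. The 12 shared an adjusted p of 0.0476 in the exact test, just under the threshold, so a few larger p-values can end all 12 calls together. As single genes, 32 of 32 proximal tubule genes were still higher and 30 of 34 matrix genes still lower after centring. The cause of the loss was not tested.

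With separate I/R libraries the share moved back was 99.04% and r was -0.9343, where each side had fewer samples. Leaving out 1 library gave 8766 to 9969 and 8465 to 9698 genes and 0 in NAT against sham; 7 to 14, 7 to 13 and 3 to 11 lists; a share of 99.03% to 99.89%; and r of -0.9779 to -0.964.

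Circadian genes in I/R against sham were up with fry (adjusted p = 0.0102), which tests against no change, and down relative to other genes with camera, so the genes' own direction did not reverse. The direction reversed for Dhcr7 in I/R against sham after quantile normalization (log2 fold change -0.01) and centring (-0.02). In NAT against sham, lists reversed with weights per library (proximal tubule adjusted p = 0.325, fatty acid oxidation 0.0285) and without both libraries numbered 2 (proximal tubule 0.0825, fatty acid oxidation 0.0036, oxidative phosphorylation 0.744). Leaving out 1 library gave 2.66e-05 to 0.437, 0.0051 to 0.899 and 1.87e-05 to 0.741 for these 3 lists, all of which reversed without NAT library 2 (0.0695, 0.0051 and 0.741), fatty acid oxidation passing in the turned direction. The cause was not tested. Libraries of the same number did not pair (r from -0.663 to 0.442). A block on the number gave 9292, 8870 and 0 genes and 8, 11 and 6 lists. With the block, endothelium was called in NAT against I/R (adjusted p = 0.0286) and proximal tubule was not in NAT against sham (0.0679). In NAT against I/R, Spp1 (adjusted p = 0.0507) and Cd3e (0.0526) then lost their limma calls and Umod gained one (0.013). Changes under a factor of 2, and larger ones in genes with a wide spread between libraries, were partly below what 5 libraries per group recover.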

Other observations

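No tests were chosen only after the result was seen in this part, which gives values alone. Of 14 neutrophil genes, 9 were highest in I/R library 4, the library with the highest injury score, and 7 reached 1 FPKM there. Ly6g and Elane were at 0.13 in it. Mmp9 was highest in NAT library 2 (1.37) and Ngp in sham library 4 (0.84). S100a8, a calcium-binding protein of neutrophils, was 42.2 FPKM in I/R library 4 and 9.89 in I/R library 1, the next highest, and S100a9 was 22.8 in I/R library 4. Csf3r, the receptor of granulocyte colony-stimulating factor, was 24.3 in I/R library 4 and 10.4 in I/R library 1.

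Of 12 genes of fat cells, 9 had their 2 highest values in I/R library 5 and NAT library 3. Pnpla2, a triglyceride lipase, was highest in I/R library 2 (86.1 FPKM), and Pck1, which the proximal tubule also expresses, in NAT library 4 (1188). Car3 was highest in NAT library 3 (81.2) and next in NAT library 4 (57.5). Cfd, adipsin, was 168 and 41.7 FPKM, Adipoq, adiponectin, 13.4 and 4.26, Retn 41.5 and 6.67, and Cidea 19.5 and 9.18 in these libraries. Ucp1, the uncoupling protein of brown fat, was 5.68 and 6.41. Adrenal genes stayed low, with Akr1b7 at 2.12 to 6.70, Star at 0.87 to 2.34 and Cyp11b1 at 0.06 or less, and so did skeletal muscle genes, with Mylpf at 1.03 to 6.73 and Ckm at 0.08 or less. Of the neurokinin and melatonin genes, Tac4 was highest, at 0.25 FPKM.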
